A study of Homo sapiens with 6 samples.

How the data were processed

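RNA was measured in SW-480, an established human colon adenocarcinoma cell line, carrying either an empty vector or a construct that overexpresses PJA2 (praja ring finger ubiquitin ligase 2, an E3 ubiquitin ligase). There were 3 libraries per group, called vector and PJA2_OE here. Per the labels, RNA was purified on silica columns and libraries were made with a SMARTer mRNA-Seq kit. The labels do not say whether the libraries keep strand, nor whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

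The count table deposited by the authors holds whole reads per gene symbol for 33893 genes, each with at least 1 read in some library. The aligner, the counter and the treatment of reads that match several places are not given in the sources used here. Per the submitters' processing notes the genome build was GRCm 38 (mm 10), a mouse build. The gene symbols and exon coordinates in the deposited count table are human, however, and 31962 of the 33247 genes matched to the GENCODE v29 annotation have exactly its GRCh38 start and end, so coordinates are given on GRCh38. In 120 cases a symbol sums loci on several chromosomes. The RPKM values deposited by the authors are reads divided by exon kilobases and by the library total in units of 1e6 reads. Recomputing them from the counts gave a largest relative difference of 1.2e-13. The authors' deposited table of their own comparison gives a p-value, an adjusted p-value and a log2 fold change for 15440 genes, and a second deposited table gives a selected part of it; per the file headers these compare overexpression with vector, and the test is not given in the sources used here. A copy of the selected table with functional annotation was not used, because its annotation covers selected genes only.

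Libraries held 41199802 to 53309759 reads assigned to genes. In such a library 3 reads, the upper limit that a count of 0 allows, correspond to 0.056 to 0.073 CPM (counts scaled to a common library total of 1e6), a bound that covers counting error only. CPM were computed on library sizes, summed over the tested genes and scaled by the trimmed mean of M-values (TMM), with factors from 0.988 to 1.013. For the mitochondrial tRNA genes and leukocyte genes CPM were computed on the unscaled totals of all genes.

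The comparison, PJA2_OE minus vector over all 6 libraries, was fitted to the counts with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided), after filterByExpr with its defaults (a minimum count of 10 and a minimum total count of 15), which left 19037 genes. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Errors of mean CPM are standard deviations (SD) over 3 libraries. Such an SD can lie below the counting error of the reads, as for PJA2 and IRF9 in vector. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over 32 lists with at least 5 tested members; camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance in one direction, were run beside it. The lists, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. The rule names PJA2 and the related gene PJA1, and up to 4 members per list with the smallest p. It also names the 10 genes higher and the 10 lower with the largest log2 fold change. These were taken among called genes with a mean of at least 5 CPM, groups that do not overlap and a proper symbol. Some genes that the rule names are not reported here. Other genes were named after their values were seen: further called members of the lists, the receptors, sensors and ligands of interferon signalling and the mitochondrial tRNA genes. The leukocyte genes are members of the fixed list of markers of other cell types.

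The alternatives were size factors by relative log expression (RLE), library size only, no filter, a filter of at least 10 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma voom, limma with a mean-variance trend on log2(RPKM + 1) of genes with a mean RPKM of at least 0.5, the same with a pseudocount of 0.1 or with no filter, an adjusted p under 0.01 and glmTreat against a 1.5-fold change. A correction for GC content was added after seeing the data. Each library's median deviation from the gene mean was taken in 30 bins of the GC content of the longest annotated transcript, interpolated, and entered as an offset. Versions with exon length as well and with exon length alone were also run. A GC value was found for 98.4% of tested and 99.1% of called genes.

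The tests were run on simulated data with the real means, dispersions and library sizes and 200 changed genes, 50 for each fold. For this comparison, over 18730 genes, edgeR recovered 58% of the genes changed 1.3-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 20 of its 188 calls were false, more than the 5% aimed at. Over 4 further simulations false calls were 5.46% to 15.5% of calls when data were drawn with gene-wise dispersions, as in the first, and 3.24% to 6.52% when drawn with trended dispersions. With a linear GC trend per library added, 72 of 241 calls were false without the GC correction, and 12 of 180 with it, over 18437 genes. In the real libraries the trend was steeper above 58% GC than below it, so these counts of false calls need not hold there. Of 3 shifted lists among 32, camera called all 3, and it called 0 of the lists that share no member with them. Genes were simulated independently of each other, so this does not check the preset correlation between genes.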

Results

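Gene expression was measured by RNA sequencing in 6 libraries of SW-480 cells, 3 with an empty vector and 3 overexpressing PJA2, an E3 ubiquitin ligase known for targeting regulatory subunits of protein kinase A. The vector libraries held 50971662, 41199802 and 43484625 reads assigned to genes and the PJA2_OE libraries 53309759, 42877963 and 44408349. Protein-coding genes took 94.7% of the reads, and mitochondrially encoded genes took 4.35% to 4.58% of the reads in each library. Read counts of libraries of the same group differed by more than sampling noise in each pair, with chi-square values of 3.8 to 12.95 per degree of freedom, so none was taken for a library deposited more than once, and each was counted as 1 sample, as the labels give them. The single comparison asks which transcripts differ in level between cells with the PJA2 construct and cells with the vector.

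PJA2 itself, the overexpressed gene, was 3.25-fold higher in PJA2_OE. Its level was 160.1 ± 0.394 CPM (counts scaled to a library total of 1e6, SD, n = 3) in vector and 520.8 ± 11.7 CPM (SD, n = 3) in PJA2_OE, a log2 fold change of 1.70 ± 0.04 (SE, edgeR adjusted p = 7.95e-20). The gene lies on chromosome 5, from 109334709 to 109409994 on the minus strand (GRCh38), and its counts are summed over 5217 bp of annotated exons, so reads of the construct and of the chromosomal gene are counted together where the construct holds those exons. PJA1, a related gene on chromosome X, had a log2 fold change of -0.11 ± 0.06 (SE), which did not pass the test (edgeR adjusted p = 0.347).

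The genes with the largest rise among well expressed genes were mostly antiviral, interferon-stimulated genes. IFIT2, which binds viral RNA, rose 16.2-fold, from 3.89 ± 0.283 to 63.2 ± 8.12 CPM (SD, n = 3 per group, log2 fold change 4.02 ± 0.10 SE, edgeR adjusted p = 2.51e-11). IFI6 rose 13.4-fold to 43.4 ± 8.05 CPM (SD, n = 3, edgeR adjusted p = 8.44e-06), and MX2, a dynamin-like GTPase that restricts viruses, rose 8.28-fold to 15.1 ± 3.29 CPM (SD, n = 3, edgeR adjusted p = 7.1e-06). IFIT1 and IFIT3, neighbours of IFIT2 on chromosome 10 between positions 89283694 and 89406486 (GRCh38), rose 6.515-fold and 4.61-fold. IRF9, the DNA-binding subunit of the complex that activates interferon-stimulated genes, rose 5.49-fold from 10.2 ± 0.0361 to 55.9 ± 5.06 CPM (SD, n = 3 per group, edgeR adjusted p = 6.83e-18). ISG15, a ubiquitin-like protein on chromosome 1, rose 4.65-fold to 74.7 ± 11.3 CPM (SD, n = 3), EPSTI1 rose 4.45-fold and the helicase DDX60 rose 3.41-fold. ATF3, a stress-induced transcription factor, rose 4.85-fold, from 3.20 ± 0.703 to 15.6 ± 1.39 CPM (SD, n = 3 per group, edgeR adjusted p = 2.36e-10).

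**Figure D1:**
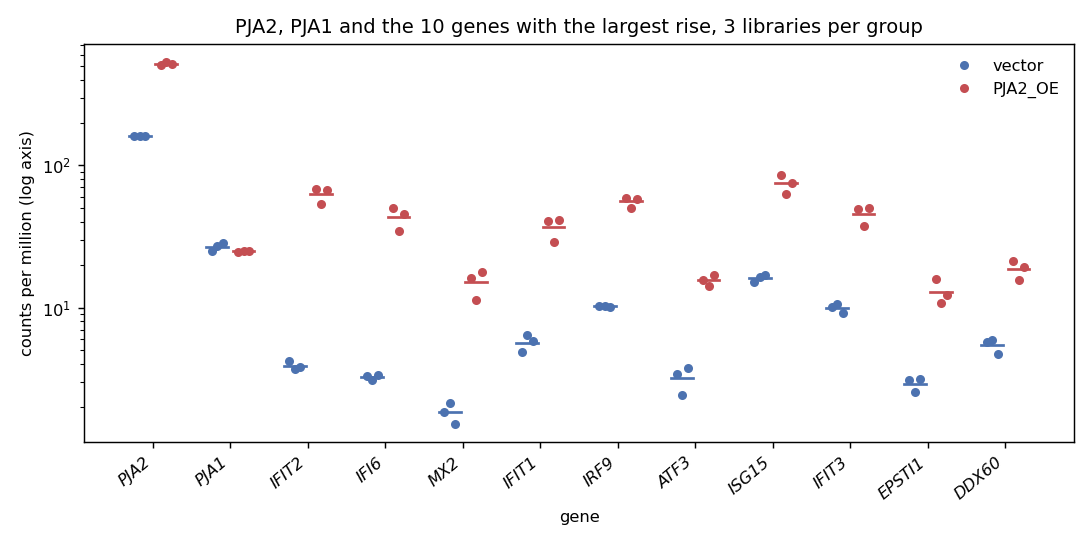
CPM (log axis) of PJA2, PJA1 and the 10 named genes with the largest rise; each point is a library (3 per group, vector blue and PJA2_OE red) and each bar the group mean. All 3 PJA2_OE libraries lay above all 3 vector libraries for each gene except PJA1, for which they lay below. The means of IFIT2 were 3.89 and 63.2 CPM.

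Over all 19037 tested genes, 1601 were called, 1153 higher and 448 lower in PJA2_OE (edgeR, adjusted p under 0.05), of which 1371 are annotated as protein-coding. Most changes were small: the median log2 fold change was 0.32 among genes called higher and -0.20 among genes called lower. At least 2-fold changes were found in 94 genes, 82 higher and 12 lower; among genes with a mean of at least 5 CPM, 33 were at least 2-fold higher and 0 at least 2-fold lower (448 genes were called lower at any size by edgeR). Of the 94 genes, 41 had a mean under 1 CPM and 3 had at most 3 reads in a group, where fitted folds depend on the prior count. The number of genes changed fell from 1601 to 735 without vector replicate 1, to 857 without vector replicate 2 and to 849 without PJA2_OE replicate 2. The groups did not overlap in CPM for 1551 of the called genes; this held for 26.1% of all tested genes, against 10% by chance.

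**Figure D2:**
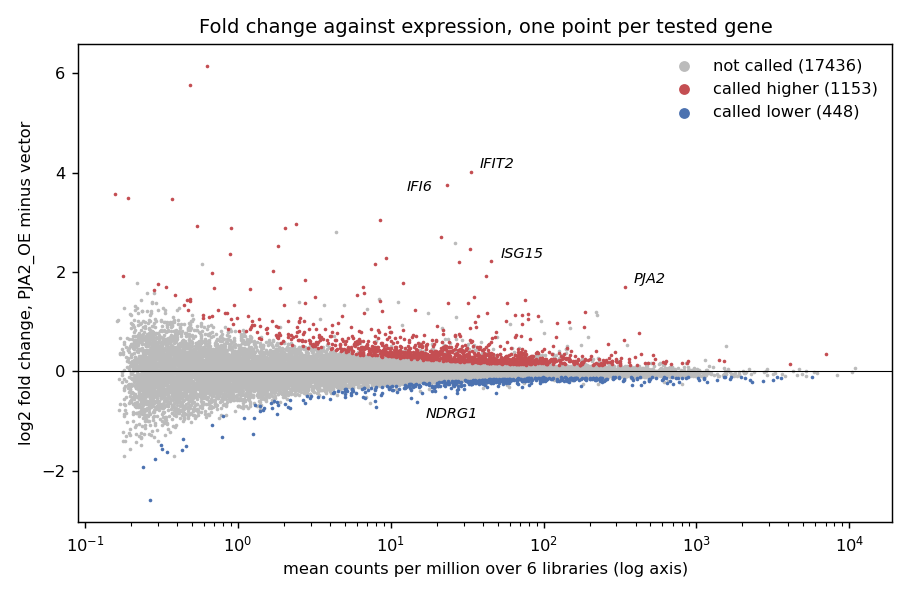
Log2 fold change (PJA2_OE minus vector) against mean CPM over 6 libraries (log axis), a point per tested gene, with called genes in red (1153 higher) and blue (448 lower) and the rest in grey. PJA2 and the labelled interferon-stimulated genes stand above the bulk of genes, whose called changes are small.

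Of the 29 tested interferon-stimulated genes of the list fixed beforehand, 28 rose and none fell, with a median log2 fold change of 1.42 (camera adjusted p = 3.47e-38, 29 adjusted over the list alone). The adjusted p was 0.167 with an estimated correlation. Beside the genes above, OAS3, which makes the activator of RNase L, rose 1.99-fold to 194.6 ± 16.4 CPM (SD, n = 3), and the RNA sensor DDX58 (RIG-I) rose 2.18-fold. XAF1 had 2 reads in vector and 176 in PJA2_OE, a ratio, scaled for library size, of 84.9 with a 95% exact binomial interval of 23.2 to 707 that covers counting error only. IRF1 had a log2 fold change of 0.23 ± 0.09 (SE) and did not pass over all genes (edgeR adjusted p = 0.106). PJA2_OE replicate 2 was the lowest of the PJA2_OE libraries for 27 of the 28 genes that rose. After a correction of each library for GC content, chosen after seeing the data, 28 of 29 were called higher.

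MHC class I presentation genes rose together: 12 of 15 were higher and none lower (median log2 fold change 0.45, camera adjusted p = 2.06e-10, 12 adjusted over the list alone), with an adjusted p of 0.153 with an estimated correlation. NLRC5, the transactivator of these genes, rose 1.95-fold from a low level of 3.07 ± 0.395 CPM (SD, n = 3, edgeR adjusted p = 1.47e-05). The peptide transporter subunit TAP2 rose 1.38-fold, the immunoproteasome subunit PSMB8 rose 1.40-fold and beta-2-microglobulin (B2M) rose 1.37-fold. HLA-B rose 2.17-fold, from 58.25 ± 3.19 to 126.2 ± 17.7 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0059), and HLA-C rose 1.56-fold, a call that ended without vector replicate 2 (edgeR adjusted p = 0.0546). The HLA genes share near-identical sequence, and how shared reads were counted is not given, so their separate values are uncertain. The list has a median GC content of 57.5%, and 11 of its 15 members were called higher after the GC correction.

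Among CREB and immediate early genes 9 of 24 rose and none fell, with a median log2 fold change of 0.30 (camera adjusted p = 7.36e-08) and 14 higher adjusted over the list alone. The list had an adjusted p of 0.153 with an estimated correlation. ATF3 led them. JUN, a subunit of the AP-1 transcription factor, rose 2.60-fold from 17.9 ± 1.40 to 46.5 ± 4.88 CPM (SD, n = 3 per group, edgeR adjusted p = 4.41e-10), and EGR1 rose 1.42-fold. In the ERK feedback list 7 of 17 members rose (camera adjusted p = 0.00235), and 8 adjusted over the list alone, with an adjusted p of 0.271 with an estimated correlation. Among them FOSL1 had a log2 fold change of 0.59 ± 0.07 (SE) and the phosphatase gene DUSP6 of 0.20 ± 0.04 (SE). EGR1 and IER3 rose and stand in both lists.

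NF-kB and chemokine genes had 5 of 16 members higher and none lower (camera adjusted p = 0.000889), and 6 adjusted over the list alone, with an adjusted p of 0.153 with an estimated correlation. They were NFKB2, 1.26-fold, RELB, 1.48-fold, TNFAIP3, 1.36-fold, ICAM1, 1.28-fold, and CSF1, 1.52-fold. RELB was not called after the GC correction (log2 fold change 0.349 ± 0.119 SE against 0.565 ± 0.133 SE before, edgeR adjusted p = 0.0855) or in 2 of the 6 fits that left out a library (largest edgeR adjusted p = 0.0652, without vector replicate 1). With the GC correction 4 members were called higher. The call of the list ended with only genes of at least 10 CPM (camera adjusted p = 0.102). YAP/TEAD targets as a list did not pass (camera adjusted p = 0.0551, adjusted p = 0.271 with an estimated correlation). Still, 5 of its 20 members rose, also 5 adjusted over the list alone, with ANKRD1 2.00-fold higher (edgeR adjusted p = 1.14e-11), NT5E 1.40-fold and CYR61 1.37-fold. It passed in fry (adjusted p = 0.00467) and after the GC correction (camera adjusted p = 0.0359).

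Several stress and growth lists shifted upward by less. Of the unfolded protein response genes 7 of 20 rose and none fell (camera adjusted p = 0.00515), and 8 were higher and 1 lower adjusted over the list alone. Its adjusted p was 0.17 with an estimated correlation. The genes included the secreted proteins MANF, 1.19-fold, and CRELD2, 1.23-fold, and the transcription factor DDIT3, 1.29-fold. ATF4 and amino acid response genes had 6 of 22 members higher (camera adjusted p = 0.0179), and 6 higher and 2 lower adjusted over the list alone. Here the adjusted p was 0.271 with an estimated correlation. The amino acid transporter gene SLC7A5 was 2.24-fold higher and ATF4 itself 1.14-fold, while CEBPB, 1.37-fold, was no longer called after the GC correction (log2 fold change 0.222 ± 0.077 SE against 0.455 ± 0.089 SE before, edgeR adjusted p = 0.0889). In the autophagy and lysosome list 3 of 22 rose (camera adjusted p = 0.0155), and 4 adjusted over the list alone, with an adjusted p of 0.289 with an estimated correlation. The autophagy receptor gene SQSTM1 rose 1.27-fold and MAP1LC3B 1.24-fold. The protease gene CTSD had a log2 fold change of 0.16 ± 0.05 (SE) that became -0.01 ± 0.04 (SE) after the GC correction. Among the 6 fits that left out a library the calls of SLC7A5 and CTSD ended in 4, that of ATF4 in 2 and that of DDIT3 in 1. The largest edgeR adjusted p were 0.167 without vector replicate 1, 0.156 and 0.0724 without PJA2_OE replicate 1, and 0.0649 without vector replicate 1. With the GC correction 6 unfolded protein response genes, 4 ATF4 genes and 2 autophagy genes were called higher and 1 ATF4 gene lower. The autophagy list did not pass without vector replicate 1 (camera adjusted p = 0.0925), without PJA2_OE replicate 3 (0.058) or with only genes of at least 10 CPM (0.0579), nor did the ATF4 list after a correction for both GC content and length (camera adjusted p = 0.0764).

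NRF2 targets had 3 of 21 higher, the ferritin gene FTH1 1.15-fold, SLC7A11 1.20-fold and AKR1B10 1.26-fold (camera adjusted p = 0.0488). Adjusted over the list alone 9 were higher and 2 lower, and the adjusted p was 0.447 with an estimated correlation. Ribosome biogenesis genes had 6 of 20 higher (camera adjusted p = 0.00399), and 8 adjusted over the list alone, with an adjusted p of 0.451 with an estimated correlation. RRP12 rose 1.16-fold and MRTO4 1.13-fold, and the list did not pass in fry (adjusted p = 0.0788). The other members that rose were RRP9, BOP1, WDR43 and NOP56. Without vector replicate 2 only RRP12 kept its call (largest edgeR adjusted p = 0.197, for WDR43). The call of NOP56 ended in 6 of 6 fits that left out a library, while the list itself passed in each of them. Epithelial genes had 4 of 22 higher (camera adjusted p = 0.0247), and 5 adjusted over the list alone, with an adjusted p of 0.252 with an estimated correlation. These were the keratin genes KRT18, 1.17-fold, and KRT8, 1.11-fold, with ELF3, 1.18-fold, and CLDN7, 1.18-fold. Replication-dependent histone genes passed as a list of 8 (camera adjusted p = 0.037, adjusted p = 0.447 with an estimated correlation) with no member called over all genes and 1 adjusted over the list alone. HIST2H2BE had a log2 fold change of 1.57 ± 0.51 (SE, edgeR adjusted p = 0.059) at under 1 CPM. After the GC correction the epithelial, histone and NRF2 lists did not pass (camera adjusted p = 0.128, 0.11 and 0.0763), while their medians were 0.039, 0.265 and 0.184 against 0.0425, 0.265 and 0.149 before it. The epithelial list also did not pass without vector replicate 1 (camera adjusted p = 0.051), without PJA2_OE replicate 3 (0.0641) or with only genes of at least 10 CPM (0.0583). The histone list did not pass in fry (adjusted p = 0.133) or in 5 of the 6 fits that left out a library, with camera adjusted p of 0.065 to 0.169 and a median of 0.097 without vector replicate 1. The NRF2 list did not pass in 4 of these fits (camera adjusted p = 0.0757 to 0.176, with a median of 0.079 without PJA2_OE replicate 3), in fry (0.0968), with only genes of at least 10 CPM (0.178, median 0.043), with RLE factors (0.0519), with library size only (0.0553) or with the replicate block (0.0514). CLDN7 was not called after the GC correction (log2 fold change 0.17 ± 0.06 SE against 0.24 ± 0.06 SE before, edgeR adjusted p = 0.102). Leaving out 1 library ended the call of AKR1B10 in 6 of 6 fits, of MRTO4 in 4 and of CLDN7 in 2, with a largest edgeR adjusted p of 0.182 without vector replicate 1, 0.125 without vector replicate 2 and 0.163 without PJA2_OE replicate 1.

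Genes that fell did so by less than 2-fold among the named genes. NDRG1, a hypoxia- and differentiation-linked gene, went from 18.0 ± 3.09 to 11.7 ± 0.556 CPM (SD, n = 3 per group), a log2 fold change of -0.61 ± 0.10 (SE, edgeR adjusted p = 0.00172). GAS7 had a log2 fold change of -0.54 ± 0.08 (SE, edgeR adjusted p = 8.3e-05), the mitophagy receptor gene BNIP3L -0.44 ± 0.06 (SE, edgeR adjusted p = 3.02e-05) and DPYSL3 -0.44 ± 0.06 (SE, edgeR adjusted p = 2.44e-05). RAB4B (-0.52), IGFL1P1 (-0.48) and ZNF169 (-0.46) also had lower log2 values; RAB4B and IGF2 overlap read-through genes and IGFL1P1 is a pseudogene, so their reads could belong to a partner. IGF2 had a log2 fold change of -0.52 ± 0.12 (SE, edgeR adjusted p = 0.0292) and EFCAB13 -0.45 ± 0.13 (SE, edgeR adjusted p = 0.0325); without vector replicate 2 neither passed (edgeR adjusted p = 0.151 and 0.256), nor did ZNF169 (edgeR adjusted p = 0.059). IGF2 and EFCAB13 also did not pass after the GC correction, with log2 fold changes of -0.60 ± 0.14 and -0.41 ± 0.13 (SE, edgeR adjusted p = 0.0665 and 0.0592).

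Lists shifted downward by small amounts. Of 45 cytosolic ribosomal protein genes 9 fell and 1 rose (camera adjusted p = 0.00515), and 12 were lower and 2 higher adjusted over the list alone. Their adjusted p was 0.641 with an estimated correlation. RPS24 had a log2 fold change of -0.27, RPL7 of -0.25 and RPL5 of -0.17. These genes have many processed pseudogenes with which reads can be shared. In the glycolysis list TPI1 (-0.27), PDK1 (-0.25) and ALDOC (-0.91, at about 1 CPM) fell and the glucose transporter gene SLC2A1 rose 1.27-fold, out of 18 members (camera adjusted p = 0.0153). Adjusted over the list alone 5 were lower and 1 higher, with an adjusted p of 0.451 with an estimated correlation. Hypoxia targets had 4 of 17 members lower, NDRG1, BNIP3L, KDM3A (-0.18) and P4HA1 (-0.17), and ADM 1.65-fold higher (camera adjusted p = 0.0179). Here 5 were lower and 1 higher adjusted over the list alone, and the adjusted p was 0.451 with an estimated correlation. In the G2/M list 6 of 25 members fell, such as HMMR (-0.18) and TOP2A (-0.17), and CDC20 and UBE2C rose (camera adjusted p = 0.0425). This became 7 lower and 2 higher adjusted over the list alone, and an adjusted p of 0.447 with an estimated correlation. After the GC correction 3 G2/M genes were lower and 3 higher, and the list did not pass (median -0.024 against -0.0699 before, camera adjusted p = 0.37). That list also lost its call in 5 of the 6 fits that left out a library (camera adjusted p = 0.0715 to 0.116), among them the fit without vector replicate 1, where 1 member was lower and 1 higher and the median was -0.041. It did not pass with the replicate block (camera adjusted p = 0.0777), with library size only (0.0515), with no filter (0.0973) or with only genes of at least 10 CPM (0.0579). After the GC correction 6 ribosomal protein genes, 2 glycolysis genes and 2 hypoxia targets were lower and 1 of each list higher. PDK1, KDM3A and P4HA1 were not called after it, with log2 fold changes of -0.20 ± 0.08, -0.13 ± 0.05 and -0.13 ± 0.05 (SE) against -0.25 ± 0.08, -0.18 ± 0.05 and -0.17 ± 0.05 (SE) before (edgeR adjusted p = 0.137, 0.138 and 0.13). Leaving out 1 library ended the call of PDK1 in 6 of 6 fits, of ALDOC in 5, of P4HA1 and UBE2C in 4, of KDM3A in 3 and of TOP2A in 1. The largest edgeR adjusted p were 0.163 for PDK1 and 0.172 for KDM3A without vector replicate 3, 0.174 for ALDOC without PJA2_OE replicate 2, 0.169 for P4HA1 without vector replicate 2, and 0.182 for UBE2C and 0.0639 for TOP2A without vector replicate 1. Without vector replicate 3 the glycolysis and hypoxia lists did not pass (camera adjusted p = 0.0835 for both). In that fit 1 glycolysis gene was lower and 1 higher (median -0.036 against -0.063 with all libraries). Hypoxia targets then had 2 lower and 1 higher (median -0.049 against -0.081). Neither list passed in fry (adjusted p = 0.0986 and 0.273). The glycolysis list also did not pass with only genes of at least 10 CPM (camera adjusted p = 0.0579). Nor did the hypoxia list without PJA2_OE replicate 3 (camera adjusted p = 0.0545). The ribosomal protein list did not pass without PJA2_OE replicate 2 (camera adjusted p = 0.0713, 4 lower and 0 higher) or in fry (adjusted p = 0.238).

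**Figure D3:**
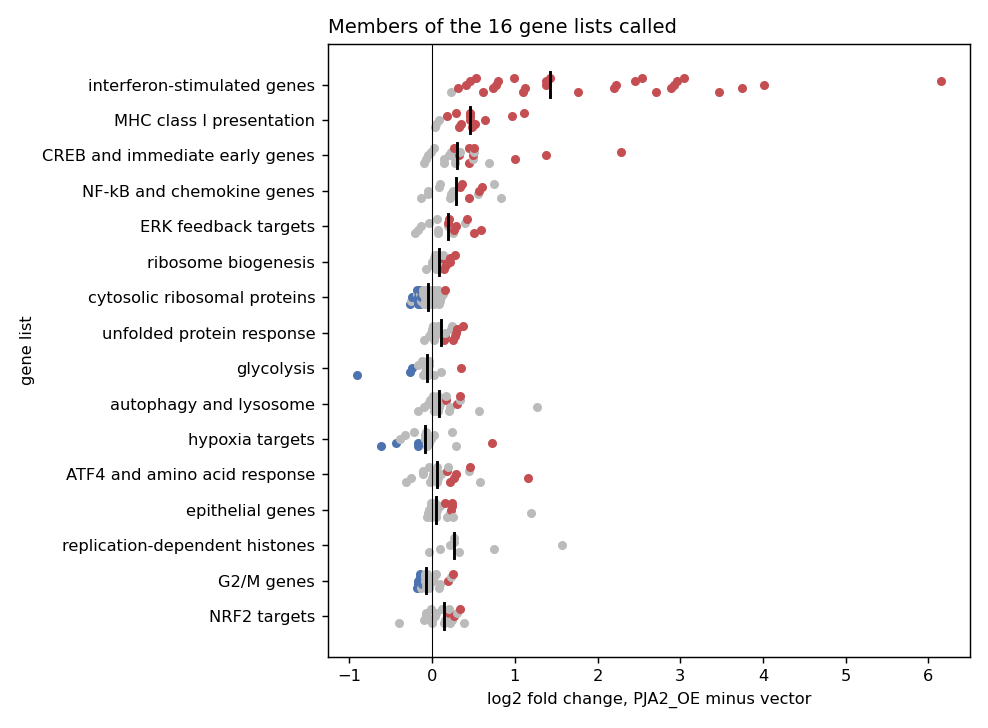
Log2 fold change (horizontal axis, PJA2_OE minus vector) of each tested member of the 16 lists called by camera; members called by edgeR are red (higher) or blue (lower), the rest grey, and a black bar marks the list median. Interferon-stimulated genes have the largest shift, with a median of 1.42, and the other lists have medians between -0.081 and 0.452.

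Lists of PJA2 substrates, protein kinase A, Wnt, p53, apoptosis and TGF-beta genes did not pass. The 8 reported PJA2 substrates had 0 members called, and 1 adjusted over the list alone (camera adjusted p = 0.915). These are RNA levels, and the protein levels of the substrates were not measured. The largest difference was in RTN4, with a log2 fold change of 0.26 ± 0.07 (SE, edgeR adjusted p = 0.053), and the kinase regulatory subunit gene PRKAR1A had -0.09 ± 0.04 (SE, edgeR adjusted p = 0.16). Among 16 genes of protein kinase A subunits and anchoring proteins PRKAR1B rose 1.22-fold, a call that ended after the GC correction (log2 fold change 0.15 ± 0.05 SE against 0.28 ± 0.05 SE before, edgeR adjusted p = 0.0849). The list had a camera adjusted p of 0.819, with 1 higher and 1 lower adjusted over the list alone. Wnt/beta-catenin targets moved both ways (camera adjusted p = 0.63), with MYC 1.24-fold and CCND1 1.19-fold higher and RNF43 (-0.18) and TNFRSF19 (-0.29) lower on the log2 scale. In that list 2 were higher and 3 lower adjusted over the list alone. The p53 targets GDF15, 1.72-fold, PLK2, 1.24-fold, and AEN, 1.21-fold, rose and CCNG1 fell (camera adjusted p = 0.296), and 5 were higher and 2 lower adjusted over the list alone. Of the apoptosis regulators PMAIP1 (NOXA) rose by 0.59 ± 0.07 (SE) on the log2 scale, and 3 rose adjusted over the list alone (camera adjusted p = 0.366, fry adjusted p = 0.0108). TGF-beta targets had 3 members higher and ITGB6 lower (camera adjusted p = 0.63, fry adjusted p = 0.0448), and 6 higher and 2 lower adjusted over the list alone. The 3 higher members, TGFB1, LTBP3 and JUNB, lost their calls after the GC correction, with log2 fold changes of 0.07 ± 0.05, -0.08 ± 0.04 and 0.24 ± 0.08 (SE) against 0.23 ± 0.05, 0.16 ± 0.05 and 0.44 ± 0.08 (SE) before (edgeR adjusted p = 0.399, 0.3 and 0.0597), while 3 other members were called higher after it. CCNG1 went from -0.17 ± 0.05 to -0.13 ± 0.05 (SE) with it and was not called (edgeR adjusted p = 0.13). ITGB6 kept most of its log2 fold change (-0.58 ± 0.17 before and -0.53 ± 0.17 SE after), with an adjusted p just past the threshold (edgeR adjusted p = 0.0578). Leaving out 1 library ended the call of AEN, ITGB6 and LTBP3 in 4 of 6 fits, of CCNG1 in 3 and of TNFRSF19 in 2. The largest edgeR adjusted p were 0.131 for AEN without vector replicate 2, 0.232 for CCNG1 without vector replicate 1, and 0.156, 0.186 and 0.06 for ITGB6, LTBP3 and TNFRSF19 without PJA2_OE replicate 2.

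S phase genes had 2 members higher and 2 lower, and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.819). The GC correction left 1 called higher, SLBP, and none lower: CDT1 went from 0.357 ± 0.086 to 0.164 ± 0.084, POLA1 from -0.141 ± 0.039 to -0.091 ± 0.037 and RRM1 from -0.125 ± 0.036 to -0.077 ± 0.036 on the log2 scale (SE, edgeR adjusted p after it 0.287, 0.159 and 0.238). Mesenchymal genes had PLAUR higher and TNC lower, the same count as adjusted over the list alone (camera adjusted p = 0.819). Intestinal genes had CDX2 and KRT20 higher and CDH17 lower, and 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.846). In the cholesterol synthesis list FDPS was lower, and 0 passed adjusted over the list alone (camera adjusted p = 0.199). The proteasome list (PSMD3) and nuclear oxidative phosphorylation list had 1 member higher each, also 1 adjusted over the list alone (camera adjusted p = 0.772 and 0.915). The call of CDH17 ended after the GC correction (log2 fold change -0.102 ± 0.044 SE against -0.151 ± 0.045 SE before, edgeR adjusted p = 0.187), with the replicate block (edgeR adjusted p = 0.0666) and in limma voom (adjusted p = 0.0583). Among the fits that left out a library the calls of FDPS, POLA1 and RRM1 ended in 5, of KRT20 and CDH17 in 4, of PSMD3 and NDUFS3 (oxidative phosphorylation) in 3, of TNC and SLBP in 2 and of CDT1 in 1 of 6. The largest edgeR adjusted p were 0.185 for FDPS, 0.257 for CDH17 and 0.0993 for NDUFS3 without vector replicate 2, 0.13 for POLA1 without PJA2_OE replicate 2, and 0.192, 0.126, 0.0775, 0.281, 0.0651 and 0.0951 for RRM1, KRT20, PSMD3, TNC, SLBP and CDT1 without vector replicate 1. Heat shock genes had 0 called, and 0 adjusted over the list alone (camera adjusted p = 0.915). Of 22 markers of fibroblasts, blood cells and endothelium 7 had enough reads to be tested, and 0 were called, also 0 adjusted over the list alone (camera adjusted p = 0.968).

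In all, camera with the preset correlation called 16 of 32 lists, 12 higher and 4 lower; fry called 13, of which 10 were shared, and camera with an estimated correlation called 0, with a smallest adjusted p of 0.15 and 6 lists at an unadjusted p under 0.05. Camera direction, median and mean differed in sign for 6 lists that did not pass, namely the PJA2 substrates, protein kinase A, Wnt, intestinal, mitochondrially encoded and other-cell lists.

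Calls were unevenly spread over GC content. Among genes with a GC content above 58%, 609 of 3679 were called higher and 18 lower, while among genes at 42% or less 109 of 4359 were called higher and 136 lower. The slope of each library's deviation on GC content was -0.055, -0.033 and -0.014 (log2 per 10 percentage points) in the vector libraries and 0.056, 0.039 and 0.008 in the PJA2_OE libraries. After the correction for GC content edgeR called 852 genes higher and 298 lower, with 208 higher and 97 lower above 58% GC, out of 18734 genes with a GC value. Without the correction the same genes gave 1142 higher and 446 lower. The correction takes off any shift that the GC-rich genes of a library share, whatever its source.

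**Figure D4:**
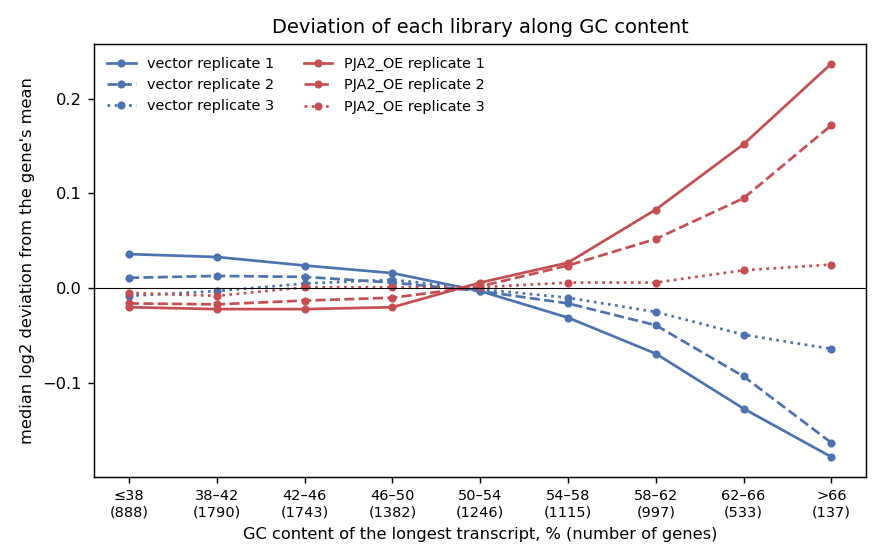
Median log2 deviation of each library from the gene's mean over 6 libraries (vertical axis) in classes of GC content of the longest transcript in percent (horizontal axis, number of genes in parentheses); vector libraries are blue, PJA2_OE libraries red, and line styles mark replicates. The 3 PJA2_OE lines lay above the 3 vector lines in each class above 50% GC and below them in each class from 38% to 50%. Slopes were farthest from 0 for replicate 1 of each group, at -0.055 and 0.056.

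The authors' deposited table of selected genes listed 1143 genes, 857 higher and 286 lower, all with an unadjusted p of at most 0.05 and an absolute log2 fold change of at least 0.32; the adjusted p in the authors' deposited table reached 0.197 among them. Here 634 of the 1143 were called in the same direction and 0 in the opposite direction by edgeR. Of the 967 genes called here and not selected there, 933 had an absolute log2 fold change under 0.32. For PJA2 the authors' deposited table gave a log2 fold change of 1.70.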

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

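The log2 fold change of PJA2 was 1.68 to 1.71 when single libraries were left out and stayed past the threshold in each alternative. The number of genes changed was 735 to 2072 when single libraries were left out (735 without vector replicate 1, 857 without vector replicate 2, 849 without PJA2_OE replicate 2, with fewer samples), against 1601 with all. It was 695 at an adjusted p under 0.01, 340 with limma on log2(RPKM + 1), 325 with log2(RPKM + 0.1) and 72 with log2(RPKM + 1) and no filter. The number changed at least 2-fold, 94, was 65 to 123 without single libraries, 30 with at least 10 CPM in at least 3 libraries, which leaves 9270 genes, 60 with DESeq2, 47 with glmTreat against 1.5-fold, and 30, 45 and 24 in the RPKM fits (log2(RPKM + 1), log2(RPKM + 0.1), and no filter); beyond the fewer genes tested by the filter, the cause was not tested. Of 16 lists called, 0 were called by camera with an estimated correlation (6 at an unadjusted p under 0.05; fry called 13), 9 with the 10 CPM filter, and 11 to 14 without single libraries. The overlap with the authors' deposited calls, 634, was 66 for genes changed at least 2-fold. Higher calls were 72% of calls, 68.9% with RLE and 73.4% with library size only.

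Deviations of same-numbered samples correlated across genes at 0.007, -0.081 and -0.058, so no clear positive correlation was seen. This cannot exclude that same-numbered samples were handled together, since differently numbered samples were not compared. Slopes on GC content, farthest from 0 for replicate 1 of each group, had opposite signs (-0.055 and 0.056), which can lower such correlations. With the replicate block the number of genes changed was 1185, 75 of them at least 2-fold, and 15 lists. It ended the calls of SLC7A5 (edgeR adjusted p = 0.2), PDK1 (0.0825), HLA-C (0.0805), AKR1B10, UBE2C, FDPS, PSMD3, ALDOC, CCNG1, CDH17, P4HA1, CTSD and CLDN7 (0.0544 to 0.0766), among others.

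Of 105 named genes called, 67 kept the call in each count-based alternative and 20 in the RPKM fits too. The GC and length corrections were added after seeing the data. After the GC correction LTBP3 went from 0.16 to -0.082 and CTSD from 0.16 to -0.006 on the log2 scale, and with length as well to -0.068 and -0.014. Neither was then called. Lists were not tested with DESeq2, limma voom or the RPKM fits. The estimated correlation gave the largest adjusted p of each called list. Apart from it, the interferon, MHC class I, CREB, ERK and unfolded protein response lists passed in each alternative that tested lists. NRF2 lost its call in 13 of these, G2/M in 11 and histones in 8. Of the 94 genes changed at least 2-fold, 41 had a mean under 1 CPM, so their folds rest on few reads.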

Other observations

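Interferon genes themselves were barely read. These genes were looked at after the lists had been seen. Type I and III interferon genes with any read, IFNB1, IFNE, IFNL1, IFNL2 and IFNL3, had 25 reads in the vector and 41 in the PJA2_OE libraries together, too few for the test. IFNE made up 21 and 19 of these, and the other 4 genes had 4 reads in vector and 22 in PJA2_OE together, each with more reads in PJA2_OE, a difference that was not tested. Of 17 receptor and signalling genes 6 rose, among them IRF9, TYK2 and IFNGR2, while IFNAR1, with a log2 fold change of -0.04 ± 0.06 (SE), JAK1, with 0.00 ± 0.05 (SE), and IRF3, with -0.04 ± 0.05 (SE), did not pass (edgeR). TYK2 was not called after the GC correction (log2 fold change 0.185 ± 0.065 SE against 0.29 ± 0.068 SE before, edgeR adjusted p = 0.0924), and leaving out 1 library ended the call of IFNGR2 in 3 and of TYK2 in 2 of 6 fits. Of 14 tested nucleic acid sensing genes 7 rose, the RNA sensors DDX58, IFIH1 and DHX58, the double-stranded RNA kinase EIF2AK2 (log2 fold change 0.39 ± 0.04 SE), the editing enzyme ADAR (0.32 ± 0.04 SE), TRIM25 and ZC3HAV1. MAVS, the adaptor of the RNA sensors, had -0.137 ± 0.045 (SE, edgeR adjusted p = 0.0596). Of a set typical of interferon gamma, GBP3 was the only called gene among 7 tested (0.25 ± 0.05 SE, edgeR adjusted p = 0.00279), and CD274 had 0.425 ± 0.134 (SE, edgeR adjusted p = 0.0505). Of the 6 genes of that set with too few reads for the test, 5 had more reads in PJA2_OE and 1 fewer, such as GBP4 with 6 in vector and 31 in PJA2_OE, CXCL11 with 2 and 15, and CXCL9 and CXCL10 with 0 and 2 each.

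In the mitochondrial genome 14 of 22 tRNA genes rose and none fell, named after their values were seen, with a median log2 fold change of 0.581 over all 22 and 0.776 over the 14. MT-TR rose by 1.44 ± 0.12, MT-TG by 1.19 ± 0.06 and MT-TL2 by 1.18 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 0.00325, 5.13e-10 and 5.4e-08). The genes with the most reads among them, MT-TC, MT-TY, MT-TN and MT-TA, with 550, 479, 407 and 305 CPM in vector, did not pass (log2 fold changes from -0.06 to -0.01). Of the 14, leaving out 1 library ended the call of MT-TL1 in 6, of MT-TI in 4, of MT-TT in 2 and of MT-TP in 1 of 6 fits. Reads of these short genes can be shared with neighbouring genes and with nuclear copies. Among the 13 mitochondrial mRNAs, a list that did not pass (camera adjusted p = 0.772, 2 up and 3 down over all genes and adjusted over the list alone), MT-ND5 had 0.35 ± 0.03 and MT-ND3 0.16 ± 0.04 (SE) higher log2 values, while MT-ND4L, MT-ATP6 and MT-CO1 were lower, and MT-ATP6 and MT-CO1 were not called after the GC correction (log2 fold changes -0.09 ± 0.03 and -0.07 ± 0.03 SE against -0.14 ± 0.03 and -0.12 ± 0.03 SE before, edgeR adjusted p = 0.085 and 0.197). Leaving out 1 library ended the call of MT-CO1 in 5 and of MT-ND3 in 4 of 6 fits (largest edgeR adjusted p = 0.186 without PJA2_OE replicate 2 and 0.118 without vector replicate 2).

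Tests of sequencing depth, of gene length, of mitochondrial RNA content and of GC content for the excess of higher calls were chosen after the results they measure were seen. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 1601 genes, 94 of them at least 2-fold, and 28 interferon-stimulated genes, and the highest of the other splits called 0 of each (edgeR, at most 1430 genes at an unadjusted p under 0.05, against 4160). For gene lists the real split called 16 and the highest other 5.

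For the rise of interferon-stimulated genes, the values argue against a GC-dependent bias of the libraries, since 28 of the 28 called members were still called higher after the GC correction. They argue against a single library as the source: 27 or 28 members were still called when any of the 6 libraries was left out. RNA of immune cells is argued against by the level of the leukocyte gene PTPRC, 0.721 CPM in PJA2_OE and 0.722 CPM in vector, while the median list member was at 24.1 CPM. CD14 and LYZ were at 0.301 and 0.153 CPM in PJA2_OE, and CD68, at 4.1 CPM in vector and 5.24 CPM in PJA2_OE, had a log2 fold change of 0.348 ± 0.121 (SE, edgeR adjusted p = 0.0795). What stays open is an effect of PJA2 itself, or of the construct, its delivery or the selection of the cells, which the design does not part from PJA2.

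For the excess of higher calls in genes of high GC content, gene length is argued against: after a correction for length alone 3.94% of the genes above 58% GC called higher lost the call and 585 kept it. Depth is argued against, since the deepest library of each group had slopes of 0.056 and -0.055. Above 58% GC, a GC-dependent library bias and a change of GC-rich transcripts in PJA2_OE cells cannot be told apart. There 66.7% of the higher calls were lost after the GC correction, leaving 203, but the correction takes off either. At 58% GC or less calls also moved with the correction, from 533 higher and 428 lower to 644 higher and 201 lower. Over all genes with a GC value, higher calls were 71.9% of calls without the correction and 74.1% with it. Slopes differed by 0.048 among the PJA2_OE libraries and by 0.068 between the group means, and those of the groups did not overlap.

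For the mitochondrial tRNA genes, more mitochondrial RNA in general is argued against by the median log2 fold change of the mRNAs, -0.041, against 0.581 over all 22 tRNA genes. GC bias is argued against by the median of the 14 called tRNA genes, 0.815 after the correction and 0.776 before. The 292 other genes under 200 bp had a median of 0.056. They cannot decide whether the PJA2_OE libraries kept more short RNA, since their reads may come from longer transcripts that overlap them. Whether the reads of the tRNA genes come from tRNAs or from longer precursors that cover them stays open. Read lengths and the counting rule are not given in the sources used here. A change in the processing of mitochondrial transcripts is a hypothesis that was not tested.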
